A study of Arundinella anomala and Arundinella fluviatilis and Arundinella hirta with 8 samples.

How the data were processed

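RNA from leaves of 8 C4 grass species was sequenced, 1 library per species. Per the labels' protocols, the libraries were made with a TruSeq RNA kit from leaves of plants grown in controlled conditions. The values used here are the deposited FPKM, fragments scaled by sequence length and by the size of the library, in 1 table for all libraries. Per the submitters' processing notes RSEM was used; its version, the aligner and its settings are not given in the sources used here. RSEM divides fragments among similar sequences by estimate, so members of a gene family can exchange values, and whole read counts cannot be recovered. Values of these grasses are listed under maize protein models, so a gene that differs in sequence from maize can be listed low or at 0. The step that tied fragments to these models was not checked here. Sequencing depth is unknown, and no interval for counting error can be given.

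The table has 36698 lines, of which 352 are at 0 in all libraries. Names are maize protein models in all but 872 lines, and 35522 names (96.8%) occur in the deposited cross-reference of identifiers. That cross-reference holds identifiers only, with no gene names or descriptions. Protein models were summed per gene to 26274 genes, 7292 of which had more than 1 line. No libraries held identical values. Libraries were matched to species by their column names.

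The enzyme names of the C4 list were therefore not taken from the files. The list of 15 maize gene models and their names was written down from general knowledge of maize C4 photosynthesis before the data were examined, and neither could be checked in the sources used here. The other gene lists set beforehand were defined by words in gene descriptions, and none of them could be run without descriptions. A further 18 gene models were recalled in the same way after the data were examined, 17 of which are in the table. They cover Rubisco and its activase, actin and other genes every cell uses, and further members of the enzyme families. Every value given for them is to be read as chosen after seeing the data, and the identity of 2 of them is unsure.

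Species were grouped by genus, the only grouping in the labels with more than 1 library: 5 *Arundinella* species and 3 species of other genera. The species was the replicate. Nothing repeats a species, so p-values measure the spread between these libraries only, and shared ancestry within *Arundinella* makes its species less than independent. Replicates were numbered in accession order and pair nothing.

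Genes with at least 1 FPKM in at least 3 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment at 0.05. Differences are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. Gene lists were tested with camera (preset inter-gene correlation 0.01), with camera using an estimated correlation, and with fry. Within-library comparisons used an exact sign-flip permutation test over the 8 species. The similarity of libraries used an exact permutation over the 56 ways to choose 5 of 8 libraries. The variation of the C4 list was set against 10000 random lists drawn from windows of 201 genes of similar mean. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

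The limma step was tested on simulated data for the comparison of *Arundinella* with the other genera, with 18780 genes of which 200 were changed. It called 0 of 50 genes changed by 2 log2 units, 2 of 50 changed by 4, 34 of 50 changed by 6 and 40 of 50 changed by 8, with 2 false calls. With no gene changed it made 0 calls, and 5.4% of genes had an unadjusted p under 0.05. In that setting the design could therefore show only very large differences. The simulated genes were drawn independently from normal distributions, without the many values of 0 or any structure shared between genes. The simulation thus cannot show that false calls are controlled in the real data. The sign-flip test gave a p under 0.05 in 6.7% of simulations with no shift and in 99.7% with a shift of 2 SD.

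The genes to be named were set before the data were examined: all members of the C4 list, the 10 strongest changes in each direction that carry a name in the files, members of the other lists, and the 10 genes with the highest mean. Without names in the files the parts that need a name gave no genes, and at most 2 identifiers are printed in each direction. The alternatives tried were other pseudocounts, filters and scalings, limma without trend or with robust estimation, the highest protein model in place of the sum, *A. anomala* and *A. hirta* averaged as 1 sample, and leaving out each library. Alternatives chosen after seeing the data were 0 treated as missing, leaving out *A. hirta* and *A. nepalensis* together, each pair of libraries compared over genes above 0 in both, other matching of the random lists, and the extent of listing as a term, a fit in which *A. hirta* is the only *Arundinella* library that bears on the genus difference. The boundary of that term, 15000 genes, was set from the data, as were the levels of 100 and 20 FPKM that define abundant genes, after several levels had been looked at.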

Results

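Leaf transcript levels were measured by RNA sequencing in 8 grass species that use C4 photosynthesis, with 1 library per species. In C4 leaves, PEP carboxylase in the mesophyll fixes carbon into acids that are broken down beside Rubisco in the bundle sheath or in comparable cells. *Arundinella* was represented by 5 species, *A. anomala*, *A. fluviatilis*, *A. hirta*, *A. nepalensis* and *A. pubescens*. The other 3 species, each from its own genus, were *Bothriochloa ischaemum*, *Capillipedium parviflorum* and *Imperata cylindrica*. Values were deposited as FPKM on maize protein models and were summed here to 26274 genes. The files give no read counts, so the depth of each library is unknown. No species had a second library, so the spread in each test is that between species, and species of a genus share ancestry. A value of 0 is given here as "listed at 0", because genes that every cell uses were also at 0 in some libraries: actin in *I. cylindrica* and cytosolic glyceraldehyde-3-phosphate dehydrogenase in *A. hirta* and *C. parviflorum*. Those reference genes were chosen after the values were seen.

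The libraries differed widely in how many genes they listed above 0. *A. anomala*, *A. fluviatilis* and *A. pubescens* listed 20468, 20388 and 20607 genes, and *A. nepalensis* listed 18023. *A. hirta* listed 10697, close to the 10198 of *I. cylindrica*, the 9681 of *B. ischaemum* and the 8142 of *C. parviflorum*. The difference was not confined to weakly expressed genes. Of 526 genes with at least 100 FPKM in each of *A. anomala*, *A. fluviatilis* and *A. pubescens*, *A. nepalensis* listed 5.7% at 0, *A. hirta* 35.2%, *I. cylindrica* 37.8%, *B. ischaemum* 46.8% and *C. parviflorum* 51.0%. Genes above 0 in all 8 libraries numbered 1586, or 6.04% of the genes.

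**Figure D1:**
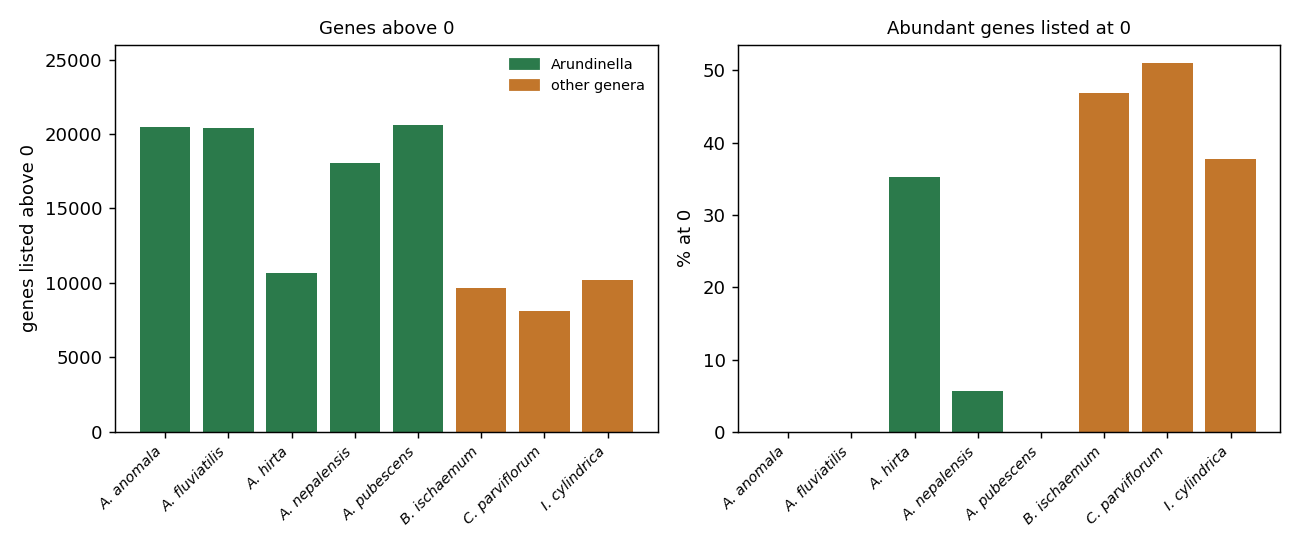
Left, number of genes listed above 0 in each of the 8 libraries. Right, percentage of 526 abundant genes listed at 0 in each library; these genes were chosen for having at least 100 FPKM in *A. anomala*, *A. fluviatilis* and *A. pubescens*, which are therefore at 0%. *A. hirta*, with 10697 genes, stands with the 3 other genera and not with the 4 other *Arundinella* libraries.

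The enzymes of the C4 cycle followed different patterns from species to species. The C4 form of PEP carboxylase (GRMZM2G083841), which makes the first carbon fixation, reached 24807 FPKM in *A. fluviatilis*, 11746 in *I. cylindrica*, 7380 in *A. pubescens* and 2285 in *A. anomala*. It stood at 10.02 FPKM in *A. nepalensis* and was listed at 0 in *A. hirta*, *B. ischaemum* and *C. parviflorum*. The C4 NADP-malic enzyme (GRMZM2G085019), which releases CO2 in the bundle sheath, was high in the same 4 libraries, at 4049 FPKM in *I. cylindrica*, 3043 in *A. fluviatilis*, 1985 in *A. anomala* and 1695 in *A. pubescens*. It was at 7.97 FPKM in *B. ischaemum*, 1.54 in *A. nepalensis* and listed at 0 in *A. hirta* and *C. parviflorum*. PEP carboxykinase (GRMZM2G001696), an alternative decarboxylating enzyme, was at 3160 FPKM in *A. fluviatilis*, 2772 in *A. anomala* and 2494 in *A. hirta*. It was at 1.42 FPKM in *A. nepalensis* and 1.25 in *A. pubescens*, and it was listed at 0 in the 3 other genera.

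Among the remaining members of the C4 list, NADP-malate dehydrogenase (GRMZM2G129513), which makes malate in the chloroplast, ranged from 2410 FPKM in *A. fluviatilis* to a listing at 0 in *A. hirta*, *B. ischaemum* and *I. cylindrica*. Carbonic anhydrase 1 (GRMZM2G121878), which supplies bicarbonate to PEP carboxylase, was at 6685 FPKM in *A. fluviatilis*, 1684 in *A. pubescens*, 1452 in *A. hirta*, 1083 in *A. anomala* and 831 in *C. parviflorum*, and at 0 in the other 3 libraries. Carbonic anhydrase 2 (GRMZM2G348512) was highest in *C. parviflorum*, at 748 FPKM, against at most 17.8 in the other libraries. Pyruvate orthophosphate dikinase (GRMZM2G306345), which regenerates PEP, was at 196 FPKM in *A. nepalensis* and between 0 and 9.90 elsewhere. A further gene model for that enzyme (GRMZM2G097457), which had the highest mean of all genes and was not on the list fixed beforehand, was at 21851 FPKM in *A. fluviatilis*, 12344 in *A. anomala*, 9941 in *I. cylindrica* and 5580 in *A. pubescens*. It was at 137 FPKM in *A. nepalensis* and at most 10.2 in the other 3. The triose phosphate translocator (GRMZM2G070605), which exports the products of photosynthesis from the chloroplast, was the steadiest member, between 857 FPKM in *A. nepalensis* and 3538 in *A. pubescens*. The PEP/phosphate translocator (GRMZM2G174107) was at 1624 FPKM in *B. ischaemum* and at most 24.8 in the other libraries. Only PEP carboxylase kinase (GRMZM2G178074), the dicarboxylate transporter DiT2 (GRMZM2G086258) and the triose phosphate translocator were above 0 in all 8 libraries, and 31 of the 120 values of the list (25.8%) were at 0.

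**Figure D2:**
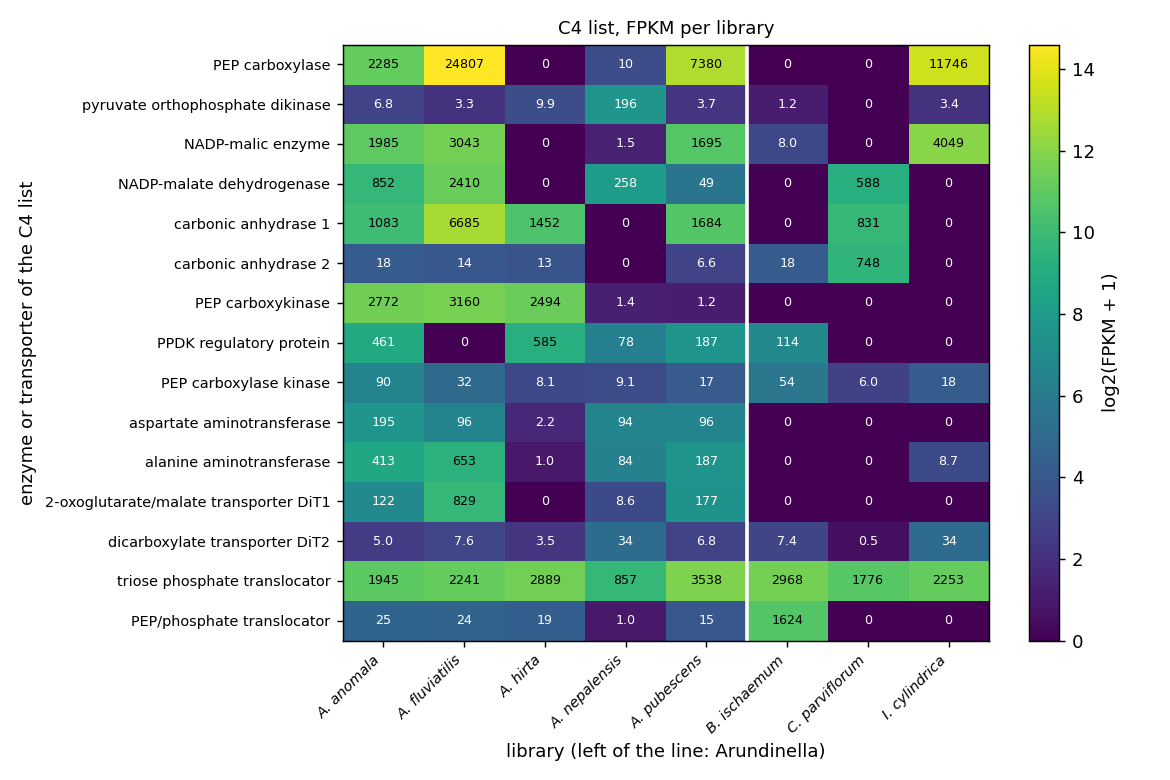
FPKM of the 15 members of the C4 list (vertical axis) in the 8 libraries (horizontal axis), with *Arundinella* left of the white line; colour gives log2(FPKM + 1) and each cell prints its FPKM. PEP carboxylase and NADP-malic enzyme are high in *A. anomala*, *A. fluviatilis*, *A. pubescens* and *I. cylindrica* and near 0 in the other 4 libraries.

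The first comparison set the 5 *Arundinella* libraries against the 3 of other genera. Of the 15 C4 genes, 13 were fitted higher in *Arundinella* and 2 lower, where 91.4% of all genes tested were fitted higher. Under quantile normalization PEP carboxylase kinase (−1.73), DiT2 (−2.03) and the PEP/phosphate translocator (−1.42) were fitted lower too. Aspartate aminotransferase (GRMZM2G094712), which makes the C4 acid aspartate, was the 1 member that passed over all genes tested (limma, adjusted p = 0.0477): it was at 195, 96.0, 2.25, 94.3 and 96.1 FPKM in *A. anomala*, *A. fluviatilis*, *A. hirta*, *A. nepalensis* and *A. pubescens* and listed at 0 in the 3 others. With p-values adjusted over the list alone, 4 members passed. Besides aspartate aminotransferase (0.0124), these were alanine aminotransferase (GRMZM2G088064), with a log2 difference of 5.51 ± 1.78 (SE) and an adjusted p of 0.0353, and PEP carboxykinase and the 2-oxoglutarate/malate transporter DiT1 (GRMZM2G383088), both listed at 0 in the 3 other libraries, at the same adjusted p. Over all genes tested, their adjusted p-values were 0.0954, 0.0956 and 0.0954. Of all 18780 genes tested, 5458 had an unadjusted limma p under 0.05. The number passing on the list alone therefore does not set the C4 genes apart from other genes. The C4 PEP carboxylase and NADP-malic enzyme did not pass by either adjustment, and for NADP-malic enzyme the log2 difference was 1.87 ± 3.05 (SE). The aspartate aminotransferase call ended when any 1 library other than *A. hirta* was left out, with adjusted p-values from 0.0783 to 0.154, and under 14 of the alternative settings in all. With any such library left out, the log2 difference of this gene stayed at 5.37 to 5.82.

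Across the transcriptome, 343 of 18780 genes tested passed (limma, Benjamini-Hochberg adjusted p), 335 of them higher and 8 lower in *Arundinella*. The files carry no names for these genes. GRMZM2G077333 was between 257 and 3511 FPKM in the 5 *Arundinella* libraries and listed at 0 in the others (adjusted p = 0.0129). In the other direction, GRMZM2G038365 was listed at 0 in all 5 *Arundinella* libraries and was at 4074, 1.32 and 2123 FPKM in *B. ischaemum*, *C. parviflorum* and *I. cylindrica* (adjusted p = 0.0483), and GRMZM2G027392 was at 165, 224 and 153 FPKM there against 38.0 FPKM in *A. pubescens* and 0 in the 4 other *Arundinella* libraries (adjusted p = 0.031). All 343 genes had *Arundinella* and other values that did not overlap, as did 12.9% of the genes tested, against 3.6% by chance.

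The comparison ran alongside the difference in listing. The median gene was fitted 1.74 log2 units higher in *Arundinella*, and 91.4% of genes were fitted higher. Of the 335 genes that passed in that direction, 275 were listed at 0 in all 3 other libraries, and 1 of the 343 was above 0 in all 8 libraries. Among all 18780 genes tested, 3637 were at 0 in all 3 other libraries and 1585 were above 0 in all 8. Values all at 0 have no spread, so such genes can pass more readily. The counts among passing genes therefore do not show a cause. The 4 libraries with more than 15000 genes listed were all *Arundinella*, and the 4 with fewer held 1 *Arundinella* library, *A. hirta*. Within the first kind there was nothing to compare, and within the second the comparison is *A. hirta* alone against the 3 others. A limma fit with the extent of listing as a term, chosen after seeing the data, amounts to that comparison of 1 library with 3, which could hardly give a call: 0 genes passed, with 1548 at an unadjusted p under 0.05, and this says little about genus. Quantile normalization gave 20 genes, 8 higher and 12 lower, with a median shift of −0.16, and median-of-ratios scaling gave 152 genes with a median shift of 1.10. Leaving out 1 library gave 1 gene without *A. anomala*, 71 without *A. fluviatilis*, 5847 without *A. hirta*, 328 without *A. nepalensis*, 90 without *A. pubescens*, 3 without *B. ischaemum*, 22 without *C. parviflorum* and 629 without *I. cylindrica*.

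As a group, the 15 C4 genes did not stand apart from the other genes in this comparison (camera with a preset correlation of 0.01, two-sided p = 0.628; p = 0.739 with an estimated correlation). Their median log2 difference of 3.86 lay above the all-gene median of 1.74, while the camera statistic was directed downwards, so median and test differed in sign. That median includes aspartate aminotransferase, PEP carboxykinase and DiT1, whose fitted values rest on the pseudocount because the other genera were at 0. Without *C. parviflorum* the median of the list was 2.05 and that of all genes 1.58. Tested on their own and not against other genes, the C4 genes moved on balance towards *Arundinella* (limma's fry, adjusted p = 0.0246; adjusted p = 0.0123 for change in either direction). Since 91.4% of all genes tested were fitted higher, the direction of fry was nearly given beforehand and does not set the C4 genes apart. With 1 list run, adjusted and unadjusted values of these list tests are equal. Under quantile normalization the camera p was 0.0146, directed upwards.

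The balance of decarboxylating enzymes separates the biochemical types of C4 photosynthesis. Of these enzymes, NADP-malic enzyme and PEP carboxykinase were compared within each library. No other was on the C4 list, so the pair does not assign a type to a species. NADP-malic enzyme exceeded PEP carboxykinase by 9.56 log2 units in *A. pubescens*, and it was at 4049 against 0 FPKM in *I. cylindrica* and 7.97 against 0 in *B. ischaemum*. In *A. hirta* PEP carboxykinase led, at 2494 FPKM against 0, or against 55.9 with both NADP-malic enzyme genes summed. The pair differed little in *A. anomala* (−0.48) and *A. fluviatilis* (−0.05), where both were abundant, and in *A. nepalensis* (0.07), where both were under 2 FPKM. Both were at 0 in *C. parviflorum*. Where 1 enzyme is at 0 the log2 difference is set by the pseudocount of 1. Over the 8 species the mean difference was 1.62 ± 7.09 (SD), smaller than its spread between species (exact two-sided sign-flip permutation test, p = 0.4688; smallest possible 0.0078). It was 0.14 without *I. cylindrica*, 0.49 without *A. pubescens* and 3.46 without *A. hirta*, and 3.98 with family members summed (exact permutation p = 0.1016).

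The C4 PEP carboxylase was set against GRMZM2G074122, the member of its family with the next highest mean. The C4 form was higher by 8.85 log2 units in *A. fluviatilis*, 7.12 in *A. pubescens* and 0.95 in *A. anomala*, and it was at 11746 FPKM against 0 in *I. cylindrica*. The other form led in *A. hirta*, where it was at 4927 FPKM against a C4 form listed at 0. It also led in *A. nepalensis*, at 240 against 10.02 FPKM, and in *B. ischaemum* and *C. parviflorum*, at 19.1 and 12.9 FPKM against 0. The mean difference, which in the 4 libraries with a value of 0 rests on the pseudocount, was 0.70 ± 8.55 (SD, n = 8; exact two-sided sign-flip permutation test, p = 0.8047). It changed sign when *A. fluviatilis*, *A. pubescens* or *I. cylindrica* was left out (−0.46, −0.22 and −1.13), and with a pseudocount of 0.1 (−0.12). Against the sum of the other family members the mean difference was −1.46.

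Whole leaf profiles were on average more alike within *Arundinella* than between it and the other genera, though not for every library. Spearman's rho across 18780 genes, which are not independent replicates, averaged 0.407 ± 0.273 (SD) over the 10 *Arundinella* pairs and 0.139 ± 0.130 over the 15 pairs between *Arundinella* and the others. The difference of 0.268 was matched or exceeded by few other assignments of the libraries, but by at least 1. Its p lay above the smallest possible, 0.0179 (exact one-sided permutation over 56 splits, p = 0.0357). The difference was smaller where zeros were left out, at 0.133 over genes above 0 in all 8 libraries and 0.14 with each pair compared over genes above 0 in both (exact permutation p = 0.0357 each). *A. hirta* was closer to *B. ischaemum* (0.282) and *C. parviflorum* (0.246) than to any *Arundinella* library (0.02 to 0.151). Over genes above 0 in both libraries this turned for *A. fluviatilis* (0.627), *A. anomala* (0.605) and *A. pubescens* (0.563), against 0.54 for *B. ischaemum* and 0.5 for *C. parviflorum*, but not for *A. nepalensis* (0.447). *I. cylindrica* correlated at 0.281 to 0.317 with the 4 *Arundinella* libraries other than *A. hirta*, above each pair of *A. hirta* within the genus. Across the 18780 genes those 4 libraries were therefore more alike as a group with *I. cylindrica* than with *A. hirta*. Among the other genera, *B. ischaemum* and *C. parviflorum* correlated at 0.371, and *I. cylindrica* with these at 0.005 and −0.016. Without *A. anomala*, *A. fluviatilis*, *A. nepalensis* or *A. pubescens* the exact permutation p was 0.0571 each, and without *B. ischaemum* or *C. parviflorum* it was 0.0952. The smallest p possible was 0.0286 when an *Arundinella* library was left out and 0.0476 when 1 of the others was.

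**Figure D3:**
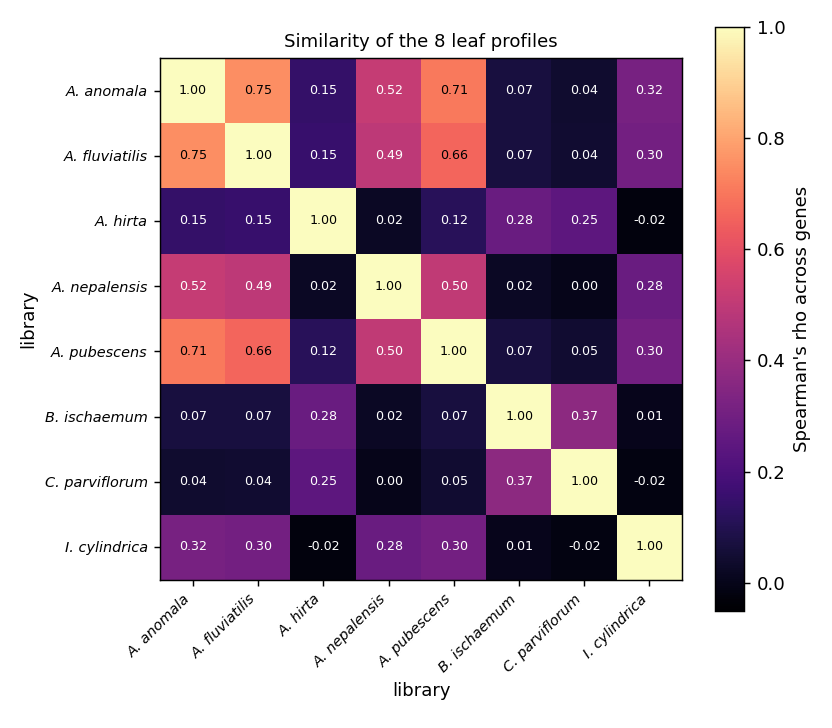
Spearman's rho across 18780 genes for each pair of the 8 libraries, in colour and as printed values. *A. anomala*, *A. fluviatilis* and *A. pubescens* are the most alike, and *A. hirta* is closer to *B. ischaemum* (0.282) than to any *Arundinella* library; over genes above 0 in both libraries the order turns for 3 of the 4, *A. nepalensis* excepted.

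The single gene models of the C4 list varied more among the 8 libraries than other genes of the same level. The median SD of log2(FPKM + 1) over the 15 genes was 3.93. Random lists of the same size matched on mean expression had a median of 2.42 and a highest value of 3.70, and 0 of 10000 reached 3.93. This describes these 8 libraries and is not a test across replicates. A value placed on another member of a family can add to the SD. In *A. hirta* the C4 PEP carboxylase was listed at 0 and GRMZM2G074122 was at 4927 FPKM. Sums over families were not set against random lists, so the variation of whole enzymes was not compared.

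Among the 10 genes with the highest mean FPKM, the C4 PEP carboxylase, the further pyruvate orthophosphate dikinase gene and a Rubisco small subunit gene (GRMZM2G113033, named after its values were seen) could be named. The small subunit of Rubisco, the enzyme that fixes CO2 in the Calvin cycle, was at 11028 FPKM in *A. nepalensis*, 5183 in *B. ischaemum*, 4764 in *A. hirta*, 4244 in *C. parviflorum*, 3209 in *A. pubescens*, 2359 in *A. fluviatilis*, 1380 in *A. anomala* and 35.8 in *I. cylindrica*.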

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

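All tests of explanations in this part were chosen after the patterns they address had been seen; the count of splits was set beforehand as a procedure but its result was known when its reading was written down. Of 37 values checked in the 5 *Arundinella* libraries, 10 had 1 library far from the other 4, by a gap of more than 0.71 of the whole range, where chance gives about 1.9. The values share libraries and are not independent.

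*A. hirta* stood far below the other *Arundinella* libraries in genes above 0 (10697, gap 0.739 of the range) and in summed FPKM (319415, gap 0.75), and far above them in abundant genes listed at 0 (35.2%, gap 0.838). The abundant genes were chosen for being high in *A. anomala*, *A. fluviatilis* and *A. pubescens*, which are at 0 by that choice. Their gap was therefore partly given beforehand. *A. hirta* was also lowest in aspartate aminotransferase (2.25 FPKM, gap 0.824) and in GRMZM2G085747, a model of unsure identity (1.68 FPKM, gap 0.881). *A. nepalensis* was far above the others in 1 pyruvate orthophosphate dikinase gene (GRMZM2G306345, 196 FPKM, gap 0.758) and in the first Rubisco small subunit gene (GRMZM2G098520, 1619 FPKM, gap 0.751). It was far below them in carbonic anhydrase 1 (listed at 0, gap 0.793) and in the PEP/phosphate translocator (1.02 FPKM, gap 0.8). Both pyruvate orthophosphate dikinase genes together were not high in *A. nepalensis*, at 333 FPKM. They were at 5583 to 21855 FPKM in *A. anomala*, *A. fluviatilis* and *A. pubescens* and at 20.1 in *A. hirta*. *A. anomala* was far below the others in a ubiquitin carrier protein gene (GRMZM2G102471, 2.11 FPKM, gap 0.865).

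The first pattern is that genes passing between *Arundinella* and the other genera lie almost wholly on the *Arundinella* side. The splits of the libraries were counted by number of genes only, so they bear on the count of calls and not on their side. Chance could not be excluded for that count. Of the 56 splits into 5 and 3 libraries, 3, the real one included, gave at least the real count of 343 genes. The highest of the others gave 4736. That split set *A. hirta*, *B. ischaemum* and *C. parviflorum* apart and called many times the real count, which points to a structure of the samples that is not genus. Incomplete listing and a real difference between genera cannot be told apart, because only 1 of the 343 genes was above 0 in all 8 libraries. With zeros left out, limma calls still lay on the *Arundinella* side. They were 28 higher and 0 lower over genes above 0 in all 8 libraries, and 48 higher and 1 lower with 0 as missing. Over the 1586 genes above 0 in all 8, the median log2(FPKM + 1) averaged 4.02 in *Arundinella* and 2.81 in the others (exact one-sided permutation p = 0.0357, smallest possible 0.0179), but *A. hirta* (3.07) was below *B. ischaemum* (3.11), so this level also went with sparse listing.

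The second pattern is that genes of at least 20 FPKM in *A. anomala*, *A. fluviatilis* and *A. pubescens* were at 0 together in *A. hirta*, *B. ischaemum* and *C. parviflorum* (phi of 0.302 to 0.397 between pairs), and nearly independently of these in *I. cylindrica* (0.014 to 0.047). Shallow sequencing as the whole cause is argued against by the most abundant eighth of these genes, of which at least 36.2% was at 0 in each of the 4 libraries. Abundance here is that in the 3 fullest libraries. From the lowest to the highest eighth, zeros fell from 57.4% to 36.2% in *A. hirta* and from 60.9% to 47.0% in *B. ischaemum*. They fell from 67.2% to 49.9% in *C. parviflorum*, and were at 36.8% and 39.5% in *I. cylindrica*. Depth as a part of the cause stays open. A shift of values between protein models of a gene as the whole cause is argued against too. At least 34.7% of the genes with more than 1 model stayed at 0 in each of the 4 libraries after summing. Such a shift as a part of the cause stays open. A difference in how these libraries were assembled, matched to maize or tabulated stays open and was not tested. A biological difference stays open too, and genus could not be tested on genes chosen for being abundant in 3 *Arundinella* libraries.

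The third pattern is that PEP carboxylase, NADP-malic enzyme, PEP carboxykinase and carbonic anhydrase were near 0 in *A. nepalensis*, while PEP carboxylase was at 0 in *A. hirta*. In *A. hirta* the values may have moved within the family, since its 4 PEP carboxylase genes sum to 136% of the lowest of the 3 fullest libraries, but in *A. nepalensis* they sum to 10.2%, which argues against it there. A general loss of abundant genes in *A. nepalensis* cannot be told apart from a loss of C4 genes: 3 of 6 abundant C4 genes and 9.4% of 520 others were under 1% of the lowest of those libraries (Fisher's exact test p = 0.0147, adjusted over 5 libraries 0.0735; the adjustment was added after the raw p was seen). PEP carboxykinase is not among those 6 and does not mark *A. nepalensis* out. It was at 1.25 FPKM in *A. pubescens* against 1.42 in *A. nepalensis*. A wrong species label also stays open, because the correlation of *A. nepalensis* with the fullest *Arundinella* libraries exceeded that with *I. cylindrica* by 0.072 at least, short of the 0.152 by which those libraries differ from *I. cylindrica*. A biological difference between species was not tested, since each has 1 library.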

How the results depend on the processing

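The tests on 0 as missing, on the extent of listing, without *A. hirta* and *A. nepalensis* together, on genes above 0 in both libraries and on other matching were chosen after seeing the data; the rest were planned. Except where stated the cause of a change was not tested. The count of 343 genes became 799 with a pseudocount of 0.1, 1 with 5, 28 over genes above 0 in all 8 libraries (1586 tested), 152 with median-of-ratios scaling, 20 with quantile normalization, 621 without trend, 2812 with *A. anomala* and *A. hirta* averaged, 49 with 0 as missing (13 of the 14 testable genes kept), 5652 without *A. hirta* and *A. nepalensis*, 0 with listing extent as a term in limma (1548 at unadjusted p under 0.05; this fit sets *A. hirta* alone against 3 libraries, which nearly fixes the outcome) and 2730 by an exact permutation per gene with unadjusted p, where chance gives 671. Leaving out 1 library gave 1 to 5847. Other filters, total scaling, robust estimation and the highest model gave 258 to 438.

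The camera p of the C4 list changed direction with median-of-ratios scaling (0.987), quantile normalization (0.0146), no filter (0.724) and listing extent (0.648). The separate fry test, which sets the list against no other genes, was directed upwards (0.0246), where 91.4% of all genes tested were fitted higher. The camera p was 0.25 to 0.995 leaving out 1 library and turned upwards without *A. nepalensis* (0.939). NADP-malic enzyme against PEP carboxykinase kept direction and side, from 0.14 to 3.46 leaving out 1 library, and was 3.98 for family sums. PEP carboxylase against its family turned to −0.12 with a pseudocount of 0.1 and −1.46 for the family sum, and ran from −1.13 to 2.55 leaving out 1 library. The similarity difference ran from 0.186 to 0.474 leaving out 1 library and was 0.133 and 0.14 over genes above 0 in all 8 and in both libraries; without *A. hirta* and *A. nepalensis* it was 0.567 with an exact permutation p of 0.05, the smallest possible there. The C4 list's percentile of variation was 100 in every planned setting and 99.8 with matching on values above 0.

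For single C4 genes, 270 values kept direction and side, 14 lost and 6 gained a call, and 33 changed sign. With listing extent as a term the log2 differences are *A. hirta* alone minus the 3 other genera. Those that changed sign were −4.51 for PEP carboxylase, −5.05 for NADP-malic enzyme, −3.07 for NADP-malate dehydrogenase and −1.09 for PEP carboxylase kinase. The others that changed sign were −0.10 for alanine aminotransferase, −0.74 for DiT2 and 0.34 for the triose phosphate translocator. Among those that stayed higher were carbonic anhydrase 1 (7.27), pyruvate orthophosphate dikinase (GRMZM2G306345, 2.37) and its regulatory protein (6.91). That comparison sets PEP carboxykinase at 2494 and aspartate aminotransferase at 2.25 FPKM in *A. hirta* against 0, without a call for either, and DiT1 at 0 against 0. PEP carboxylase kinase was at −1.02, −0.87 and −1.73 with total, median-of-ratios and quantile scaling, DiT2 at −0.62, −0.60 and −2.03, and the PEP/phosphate translocator at −0.36 and −1.42 with the last 2. A pseudocount of 5 gave −0.004 for DiT2 and −0.85 for the PEP/phosphate translocator, the highest model −0.079 for DiT2, and averaging *A. anomala* and *A. hirta* −0.017 for that translocator. Without *A. hirta* and *A. nepalensis* DiT2 was at −0.034 and the triose phosphate translocator at 0.13. Leaving out 1 library, ranges that crossed 0 were −0.65 to 5.34 for NADP-malic enzyme, −3.90 to 0.87 for carbonic anhydrase 2, −0.55 to 0.93 for PEP carboxylase kinase, −0.91 to 1.38 for DiT2, −0.33 to 0.18 for the triose phosphate translocator and −1.60 to 3.73 for the PEP/phosphate translocator. Depth is unknown, so no limit of detection can be given for a gene listed at 0.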

Other observations

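All tests and gene choices in this part were made after the data were seen. Rubisco and the C4 PEP carboxylase were highest in different libraries. Summed over both small subunit genes, Rubisco was at 12648 FPKM in *A. nepalensis*, where the C4 PEP carboxylase was at 10.02, and at 36.7 FPKM in *I. cylindrica*, where PEP carboxylase was at 11746. Rubisco activase, which keeps Rubisco active, was likewise highest in *A. nepalensis*, at 7676 FPKM over both genes, followed by 1590 in *A. fluviatilis*, 548 in *A. pubescens* and 153 in *A. anomala*. It was at 13.3 FPKM in *A. hirta*, 5.87 in *B. ischaemum* and listed at 0 in *C. parviflorum* and *I. cylindrica*. No relation across libraries was tested, and genes every cell uses varied as well: the ubiquitin carrier protein was at 985 FPKM in *A. nepalensis*, 2.11 in *A. anomala* and 0 in *I. cylindrica*.

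Family members were summed for 4 C4 enzymes, and all are given here. Both carbonic anhydrase genes together were at 6699 FPKM in *A. fluviatilis*, 1690 in *A. pubescens*, 1579 in *C. parviflorum*, 1464 in *A. hirta*, 1100 in *A. anomala* and 17.6 in *B. ischaemum*, and listed at 0 in *A. nepalensis* and *I. cylindrica*. Both pyruvate orthophosphate dikinase genes together were at 21855 FPKM in *A. fluviatilis*, 12351 in *A. anomala*, 9944 in *I. cylindrica* and 5583 in *A. pubescens*, against 333 in *A. nepalensis*, 20.1 in *A. hirta*, 6.15 in *C. parviflorum* and 3.95 in *B. ischaemum*. Both NADP-malic enzyme genes together were at 5323 FPKM in *A. fluviatilis*, 4113 in *I. cylindrica*, 2900 in *A. anomala* and 1716 in *A. pubescens*, against 72.1 in *C. parviflorum*, 58.8 in *A. nepalensis*, 55.9 in *A. hirta* and 16.2 in *B. ischaemum*. The 4 PEP carboxylase genes together were at 25024 FPKM in *A. fluviatilis*, 11807 in *I. cylindrica*, 8237 in *A. pubescens*, 5048 in *A. hirta* and 3713 in *A. anomala*, against 378 in *A. nepalensis*, 90.1 in *B. ischaemum* and 63.0 in *C. parviflorum*. All 8 species are C4 plants per the series description, so levels this low in a leaf are values to look at again.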
